A study of Mus with 6 samples.

How the data were processed

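RNA was sequenced from CD45-negative, CD31-positive endothelial cells isolated by magnetic sorting from mouse brain tumours. The tumours grew from CT2A cells, a mouse glioma line labelled with GFP and injected into the brains of C57BL/6 mice aged 6 weeks. Per the labels, 2 samples came from control mice and 4 from mice given LGK974, an inhibitor of Porcupine, the acyltransferase that Wnt proteins need in order to be secreted. The design text has dosing from day 21 with saline or LGK974 at 2.5 mg/kg by mouth on 4 days in a row and tumour collection on day 25. The characteristics of the control samples give the treatment as none, so which control animals received saline rests on the design text. Samples were grouped by the words control and LGK974 in their titles, and the replicate numbers are those at the end of the titles. The titles also carry a second sample numbering with gaps, and whether samples were left out is not known.

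The deposited values are FPKM per gene, per the file headers, in 1 table of all 6 samples and in 6 tables of 1 sample each, which held the same values as the series table. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, StringTie 1.3.1c and the mouse build GRCm38, with no roles. The annotation and the step from transcripts to genes are not given in the sources used here. Of the 55335 genes in the table, 17023 carried values with more than 6 decimals, so some gene values were computed further after a first rounding. A gene's FPKM can therefore depend on how its transcripts were assembled and combined, most of all for short RNAs inside host genes and for overlapping genes. FPKM also makes each gene's value depend on the share of reads taken by the most abundant genes. Gene symbols were those in the table, where 3225 genes had none.

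FPKM is not a count, so no count model was used. The absolute read depth of each library is unknown. Relative depth was read from the smallest steps between low values: 1 read was worth the least in control replicate 2, and the other depths relative to it were 74.8% for control replicate 1 and 87.3%, 78.0%, 99.1% and 73.1% for LGK974 replicates 1 to 4. Each of these ratios rests on the most frequent step ratio, shared by 51 to 58 of 4387 to 4863 low genes, and is approximate. Both groups thus held libraries at the lower and the upper end of the depths.

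LGK974 was compared with control with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with an intensity trend and no covariate. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 13450. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are differences on the log2(FPKM + 1) scale, LGK974 minus control, and understate the change of low genes. With 2 against 4 libraries there are 15 splits, so an exact two-sided permutation test cannot give a p below 0.0667, and such p-values are given only as a description. P-values measure the spread between these samples, since the labels do not tie each library to its own animal. Recovery was examined on simulated values built on the same 13450 genes, with 2000 changed genes at each size, pooled over repeated runs that each changed a small part of them. Changed genes were drawn only from those of higher mean expression, and the noise was independent between genes. The fit recovered 0% of genes changed by 0.5 and 50.75% of those changed by 1 on the log2 scale. It recovered 89.6% of those changed by 2 and 96.05% of those changed by 3.

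The gene lists, the rule for named genes, the tests and most of the alternative settings were fixed before the data were examined. The 41 lists cover Wnt signalling, the brain endothelial barrier, vessel types and states, other cell functions and markers of the cell types that the sort could hold. The 35 lists with at least 5 measured genes were tested with camera, a competitive test against all other genes, at its preset correlation of 0.01. Camera with an estimated correlation and the self-contained test fry were run beside it. Counts of members are given over all genes tested and adjusted over the list alone. The adjustment over a list alone does not correct for the number of lists. Named genes are up to 10 in each direction among those past the threshold with no overlap between the groups, unnamed gene models and sex-linked genes left out. Where fewer than 5 passed, those with the smallest p were added up to 5. The rule further takes 12 readout genes of Wnt signalling and the barrier, and up to 4 members with the smallest p of each list past its test. It gave 82 genes, of which some are not reported here. Members named from other lists, and those named beyond the rule as the extremes of a list or as abundant markers, were chosen after their values were seen. Coordinates come from RefSeq on GRCm38.p6, matched by symbol, with a match for all 82 genes.

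The alternatives were other pseudocounts, no filter or a stricter filter, rescaling each library to a common sum, median-of-ratios scaling, quantile normalization, limma without trend, robust moderation, array weights, the replicate number as a block, and each library left out in turn. Added after seeing the data were a fit without the 2 libraries highest in the choroid plexus gene Ttr, a covariate of 6 choroid plexus genes and a covariate of 10 barrier genes outside the Wnt target list.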

Results

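Endothelial cells sorted from CT2A gliomas were profiled in 2 samples from control mice and 4 from mice treated with LGK974. Summed FPKM was 315313 and 280374 in the control libraries and ran from 266705 to 316580 in the LGK974 libraries, and 13142 to 13571 genes reached 1 FPKM per library. Read totals are unknown, and the relative depths recovered from the values put every library at 73.1% or more of the deepest one. Pecam1, which encodes the CD31 used for sorting, was 155 ± 3.16 FPKM in control (SD, n = 2) and 211 ± 24.8 with LGK974 (SD, n = 4). Correlations between libraries across genes, which are not independent replicates, were 0.961 within control, 0.935 to 0.976 within LGK974 and 0.943 to 0.977 between the groups.

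The comparison asked which endothelial transcripts differ when Wnt secretion is inhibited for 4 days in an established tumour. The lists of Wnt targets and of brain barrier genes were lower as groups with LGK974, and those of angiogenic tip-like, activated venous and interferon-response genes were higher, by camera at its preset correlation. None of these 5 calls held with an estimated correlation (adjusted p = 0.62 for each), and the interferon list turned sign without control replicate 1 (adjusted p = 0.958). Mfsd2a, the lipid transporter that restrains transcytosis at the blood-brain barrier, was 65.1 ± 2.88 FPKM in control (SD, n = 2) and 32.8 ± 7.83 with LGK974 (SD, n = 4). Plvap, a component of the diaphragms of fenestrae and caveolae that mature brain capillaries lack, was 32.6 ± 0.576 FPKM in control and 104 ± 64.9 with LGK974. For both genes all 4 LGK974 libraries lay outside the control values, but of 13450 genes tested 0 rose and 2 fell, the small nucleolar RNA Snora7a and the kinase gene Gsk3b.

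Over all genes, limma gave 546 at an unadjusted p under 0.05, 218 higher and 328 lower with LGK974, where 672 would be expected by chance. Groups did not overlap for 12.65% of the genes, against 13.33% by chance. Of these genes 543 were higher and 1158 lower with LGK974, a split that became 863 and 697 under median-of-ratios scaling, 872 and 743 under quantile normalization, and 536 and 678 with libraries rescaled to a common sum. The number of lower genes was 0 without control replicate 2 and 1 without both libraries highest in Ttr, where the gene called was the gene model Gm20431. The number of higher genes was 2 without control replicate 1.

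Snora7a (ENSMUSG00000064563), a guide RNA for pseudouridylation, fell from 7.03 ± 0.462 FPKM in control to 0.180 ± 0.0219 with LGK974. Its log2 fold change was -2.77 (SE 0.13, limma adjusted p = 0.00234). It lies on chromosome 6 at 115807975 to 115808103 in GRCm38.p6, inside the ribosomal protein gene Rpl32, which was 287 FPKM in control and 285 with LGK974. Gsk3b (ENSMUSG00000022812) encodes a kinase of the complex that marks beta-catenin for degradation. It fell from 12.7 ± 1.42 to 3.89 ± 0.178 FPKM, a log2 fold change of -1.49 (SE 0.11, limma adjusted p = 0.0257). It lies on chromosome 16 at 38089001 to 38246084 and overlaps BC031361 and Gm25617. Without any 1 of the 6 libraries the adjusted p of Gsk3b missed the threshold, at 0.0941 to 0.141, while its log2 fold change stayed between -1.59 and -1.38. Snora7a missed it without control replicate 2, with an adjusted p of 0.0833.

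The genes with the next smallest p did not pass. Higher in all 4 LGK974 libraries than in both controls were Pcdhb22 (log2 fold change 1.38), Jade1 (1.10), Fam220a (1.41), Mir7669 (0.97) and Ldah (1.09). Lower in all 4 were Paqr7 (-1.51), Pik3ip1 (-0.95) and Snord83b (-0.98), the last a small nucleolar RNA inside Rpl3. Their limma adjusted p-values were 0.233 to 0.399.

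**Figure D1:**
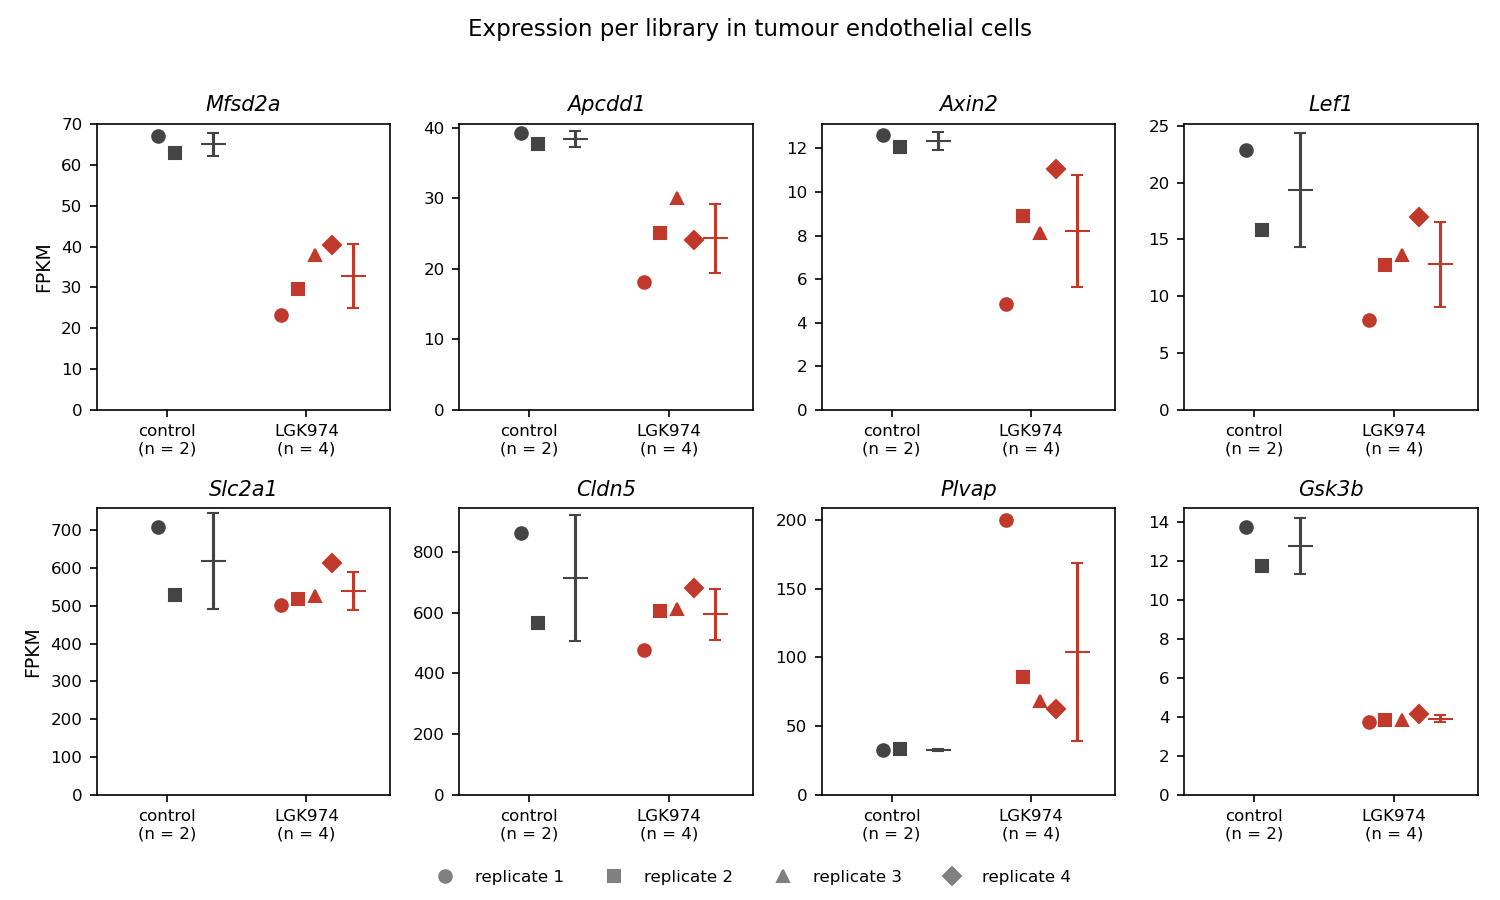
Expression in FPKM of 8 genes per library, with control in grey (n = 2) and LGK974 in red (n = 4); symbols mark replicates and bars show mean ± SD. All 4 LGK974 libraries lie below both controls for Mfsd2a, Apcdd1, Axin2 and Gsk3b and above them for Plvap, and the groups overlap for Lef1, Slc2a1 and Cldn5; of these genes Gsk3b alone passed the test over all genes.

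The Wnt target list fell as a group. Of its 18 measured members 15 were lower and 3 higher, with a median log2 fold change of -0.28, and 0 passed the gene test over all genes or adjusted over the list alone (camera adjusted p = 0.00962; adjusted p = 0.62 with an estimated correlation). Its mean was lower in all 4 LGK974 libraries than in both controls. Apcdd1, a Wnt-induced membrane inhibitor of the pathway, was 38.4 ± 1.11 FPKM in control and 24.3 ± 4.87 with LGK974 (log2 fold change -0.66, SE 0.19). Axin2, a feedback inhibitor, was 12.3 ± 0.402 and 8.22 ± 2.57 FPKM (log2 fold change -0.58, SE 0.27), with all LGK974 libraries below control. The transcription factor genes Lef1 and Tcf7 had log2 fold changes of -0.58 and -0.50, Nkd1 -0.59 and Dkk2 -0.43. Tnfrsf19 was at -0.33, and Ccnd1 and Myc, which many other signals also drive, at 0.01 and -0.04. Without control replicate 2 the list's adjusted p was 0.0701.

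Genes of Wnt ligands and secretion, and those of Wnt receptors and transduction, did not pass as groups. Of 26 ligand and secretion genes 5 were measured, 4 of them lower, with a median log2 fold change of -0.18 (camera adjusted p = 0.275). Porcn, which encodes the target of LGK974, was 2.50 ± 0.517 FPKM in control and 1.91 ± 0.478 with LGK974. Of 25 measured receptor and transduction genes 16 were lower, with a median of -0.06 (adjusted p = 0.184), and 1 passed over all genes and adjusted over the list alone, Gsk3b. This list was the only 1 of 35 past fry's test for changes in either direction (adjusted p = 0.00018). It holds Gsk3b, and every other member had a limma adjusted p over the list alone of 0.485 or more. The call therefore does not show a change in the list beyond Gsk3b. Nor does it exclude one, as fry was not run without that gene.

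The brain endothelial barrier list fell as a group. Of 44 measured members 39 were lower, with a median log2 fold change of -0.30, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 1.48e-05; adjusted p = 0.62 with an estimated correlation). The groups overlapped in the list mean: relative to the control mean it was 0.15 and -0.15 in the controls, -0.67 and -0.29 in LGK974 replicates 1 and 2, and -0.12 and -0.11 in replicates 3 and 4. Mfsd2a had a log2 fold change of -0.996 (SE 0.22, limma adjusted p = 0.938) and an exact permutation p of 0.0667, the smallest these groups allow. It lies on chromosome 4 at 122946850 to 122961194. Slc7a1, a transporter of cationic amino acids, was 27.8 ± 0.823 FPKM in control and 20.2 ± 2.04 with LGK974 (log2 fold change -0.45), and the transcription factor gene Foxf2 was at -0.31. The glucose transporter Slc2a1 was 619 ± 127 and 540 ± 49.7 FPKM (log2 fold change -0.18), the tight junction gene Cldn5 was at -0.25 and the efflux pump Abcb1a at -0.20. Of the 44 genes 3 are also on the Wnt target list, Apcdd1, Lef1 and Tnfrsf19. Without control replicate 1 the adjusted p of the list was 0.216, and Slc2a1 and Cldn5 were then at 0.03 and 0.06.

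Lipid uptake genes did not pass as a group (12 of 21 lower, median log2 fold change -0.09, adjusted p = 0.462), but adjusted over the list alone 2 fell, Mfsd2a (adjusted p = 0.0335) and Lrp8 (adjusted p = 0.0243). For Mfsd2a this depended on the list, as its limma p adjusted over the barrier list alone was 0.14. Lrp8, a receptor for reelin and apolipoprotein E, was 10.6 ± 0.156 FPKM in control and 4.04 ± 1.17 with LGK974 (log2 fold change -1.24, SE 0.23). Neither passed over all genes. Junction genes did not pass either (13 of 21 higher, median 0.05, adjusted p = 0.142; adjusted p = 0.62 with an estimated correlation), except as higher without both libraries highest in Ttr (0.0132). The list of caveolae and vesicle genes rose as a group, with 16 of 25 higher and a median of 0.11 (camera adjusted p = 0.044; adjusted p = 0.62 with an estimated correlation). The 1 member past the test adjusted over the list alone was Lrp8, which fell (adjusted p = 0.0289), and 0 passed over all genes. Plvap, on chromosome 8 at 71497753 to 71511806 and overlapping Gtpbp3, had a log2 fold change of 1.48 (SE 0.45). The caveolar coat genes Cav1 and Ehd2 were at 0.39 and 0.30, and Stx4a at -0.23. This list was not past the threshold in 9 of 20 alternative settings, among them quantile normalization (adjusted p = 0.167).

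Angiogenic tip-like genes rose as a group, 26 of 29 being higher, with a median log2 fold change of 0.28 (camera adjusted p = 1.48e-05; adjusted p = 0.62 with an estimated correlation). None passed alone, 0 over all genes and 0 adjusted over the list alone. Trp53i11 had a log2 fold change of 1.05, Ramp3 0.57, the Notch ligand Dll4 0.51 and the VEGF receptor Kdr 0.32. Except for Ramp3, the groups overlapped for these genes, with control replicate 2 above the lowest LGK974 library. The list mean was highest in LGK974 replicate 1, at 1.06 above the control mean, while LGK974 replicates 3 and 4, at 0.19 and -0.26, lay between or near the controls, at -0.27 and 0.27. Without control replicate 1 its adjusted p was 0.14. The list of VEGF ligands, their receptors and Tie genes had 11 of 17 higher, with a median of 0.10 (camera adjusted p = 0.044; adjusted p = 0.62 with an estimated correlation). Its members went both ways, with Nrp2 at 0.33 and Ptprb at 0.29 but the ligands Vegfb at -0.44 and Vegfd at -0.34. The VEGF list missed the threshold in 12 of 20 alternative settings, all 3 other scalings included. Of its 17 genes 6 are also pan-endothelial markers and 5 are on the tip-like list. The pan-endothelial markers had a median of 0.158, above the VEGF, caveolae (0.111), arterial (0.104) and Notch (0.073) lists. The medians of the venous (0.162) and tip-like (0.281) lists were larger. Whether any of these lists rose beyond the pan-endothelial markers was not tested.

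Venous and activated endothelial genes rose as a group, with a median log2 fold change of 0.16 and 11 of 20 higher (camera adjusted p = 0.00177; adjusted p = 0.62 with an estimated correlation). The leukocyte adhesion gene Selp was 13.4 ± 3.87 FPKM in control and 29.5 ± 8.01 with LGK974 (log2 fold change 1.07, SE 0.27), and Sele was at 0.75, both higher in all 4 LGK974 libraries. Slc38a5, which is also on the barrier list, was at -0.62. Its groups overlapped, at 106 and 61.8 FPKM in control and 39.4 to 64.9 with LGK974. Arterial genes rose as a group, with 12 of 21 higher and a median of 0.10 (camera adjusted p = 0.00962, and 0.62 with an estimated correlation). The groups overlapped in the arterial list mean. Relative to the control mean it was 0.206 and -0.206 in the controls and -0.207, 0.13, 0.182 and 0.321 in LGK974 replicates 1 to 4. The gap junction gene Gja5 was 1.78 ± 0.0177 FPKM in control and 6.12 ± 2.11 with LGK974 (log2 fold change 1.299, SE 0.30), and Efnb2, Sema3g and Mgp were at 0.48, 0.53 and 0.53. Notch pathway genes had 9 of 14 higher and a median of 0.07 (adjusted p = 0.044; adjusted p = 0.62 with an estimated correlation), with Dll1 at 0.48, Notch4 at 0.39 and Notch1 at 0.22; 6 of the 14 are also on the arterial list. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. Without control replicate 2 the adjusted p was 0.0667 for the venous, 0.817 for the arterial and 0.295 for the Notch list. Without LGK974 replicate 4 it was 0.0919 for the arterial and 0.135 for the Notch list, and the Notch list missed the threshold in 9 of 20 alternative settings.

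**Figure D2:**
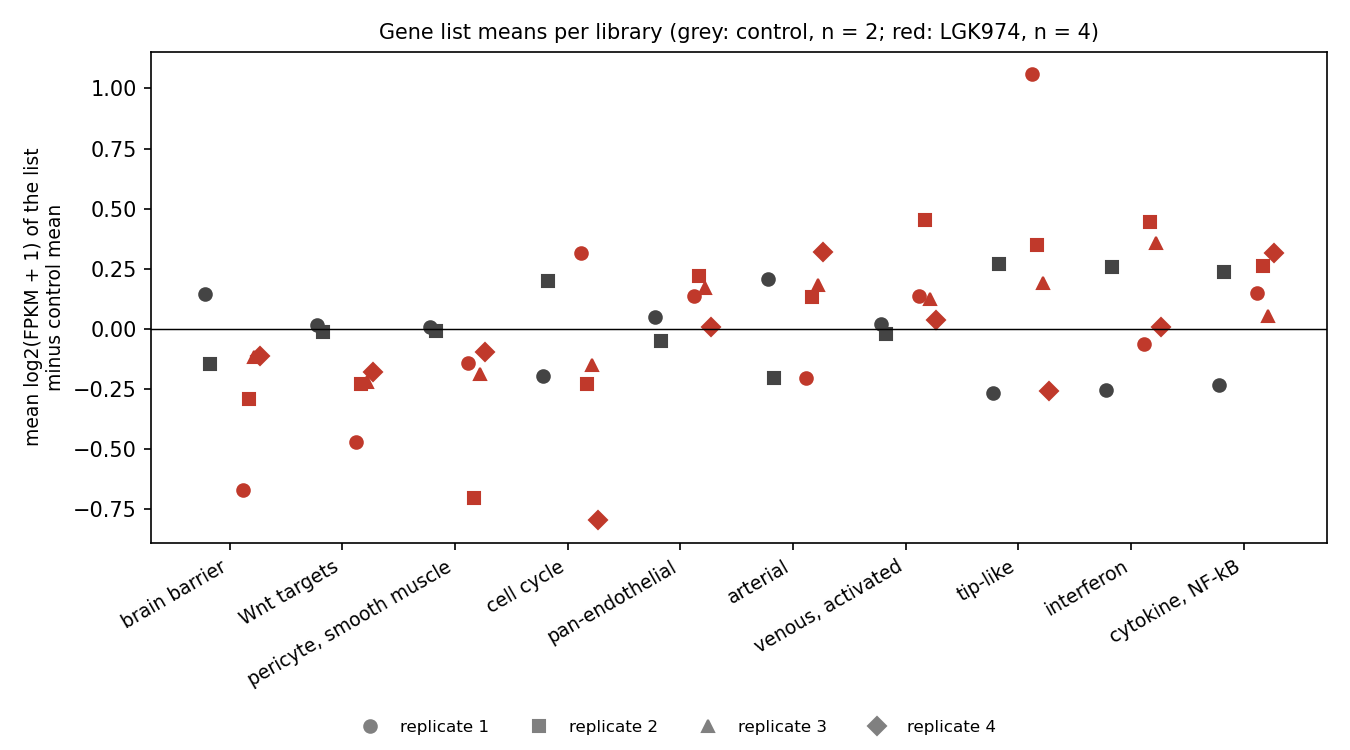
Mean log2(FPKM + 1) of 10 gene lists in each library, minus the mean of the controls; control libraries are grey (n = 2), LGK974 libraries red (n = 4), and symbols mark replicates. The Wnt target means of the 4 LGK974 libraries, from -0.47 to -0.18, lie below both controls, and the tip-like means run from -0.26 to 1.06 against -0.27 and 0.27 in control.

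Interferon-response genes rose as a group, with 27 of 30 higher and a median log2 fold change of 0.17 (camera adjusted p = 1.48e-05; adjusted p = 0.62 with an estimated correlation). Ifi27l2a was at 0.59, Rsad2 at 0.42 and Ifi44 at 0.30. Cytokine and NF-kB genes also rose as a group, 20 of 24 being higher, with a median of 0.23 (adjusted p = 0.000817; adjusted p = 0.62 with an estimated correlation). Il6 was at 0.62, the chemokine genes Cxcl2 and Cxcl1 at 0.57 and 0.32, and Birc3 at 0.37. In both lists 0 genes passed over all genes or adjusted over the list alone. Control replicate 1 was the lowest of the 6 libraries in both list means, and without it the adjusted p was 0.958 for the interferon list, then with the opposite sign, and 0.543 for the cytokine list. T and NK cell markers were lowest in LGK974 replicate 1 and control replicate 1 and highest in LGK974 replicates 2 and 3, which were also the 2 highest in the interferon list. Antigen presentation genes did not pass (12 of 17 higher, median 0.08, adjusted p = 0.14; adjusted p = 0.753 with an estimated correlation). They passed as higher with array weights (0.00956), without control replicate 2 (0.00177), without LGK974 replicate 1 (0.0147) and without LGK974 replicate 4 (0.038).

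Cell cycle genes fell as a group, 29 of 30 being lower, with a median log2 fold change of -0.22 (camera adjusted p = 0.044; adjusted p = 0.769 with an estimated correlation). Ccne1 was at -0.39, Rrm2 and Aurkb at -0.37 and Ube2c at -0.30, and 0 passed over all genes or adjusted over the list alone. LGK974 replicate 4 was the lowest library and LGK974 replicate 1 the highest. Without replicate 4 the direction turned (adjusted p = 0.731), as it did without control replicate 2 (adjusted p = 0.817). Matrix and mesenchymal genes had 21 of 30 higher and a median of 0.04 (adjusted p = 0.0213; adjusted p = 0.645 with an estimated correlation), with Col5a2 at 0.56, Zeb1 at 0.34, Snai1 at 0.30 and Cdh2 at -0.40. Hypoxia and glycolysis genes had 16 of 29 higher and a median of 0.03 (adjusted p = 0.043; adjusted p = 0.645 with an estimated correlation). The lactate exporter Slc16a3 was at 0.56, Pfkp at 0.33, Ldha at 0.14 and Pfkfb3 at -0.36. In these 2 lists 0 genes passed over all genes or adjusted over the list alone. Without control replicate 1 both had an adjusted p of 0.958, the matrix list with the opposite sign, and without LGK974 replicate 1 it was 0.58 for the matrix and 0.281 for the hypoxia list.

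Other functional lists did not pass. Nuclear-encoded respiratory chain genes were lower in 25 of 27 cases, with a median log2 fold change of -0.08 (camera adjusted p = 0.0652), and passed without a filter (0.012), under quantile normalization (0.0413), with array weights (0.033), without control replicate 2 (0.0233) and without LGK974 replicate 4 (0.011); with an estimated correlation its adjusted p was 0.645. The 13 mitochondrially encoded transcripts were all lower, with a median of -0.33 (adjusted p = 0.0652). That list passed with libraries rescaled to a common sum (0.00613), under median-of-ratios scaling (0.0384), with array weights (0.0228), without control replicate 2 (0.000236) and without LGK974 replicate 4 (0.00129), and turned sign without control replicate 1 (0.23). With an estimated correlation its adjusted p was 0.745. Apoptosis and p53 genes had a median of -0.16 (adjusted p = 0.269), unfolded protein response genes -0.06 (adjusted p = 0.908) and immediate early genes, which tissue dissociation can induce, -0.09 (adjusted p = 0.431). The immediate early list passed as lower without control replicate 2 (0.0325) and without LGK974 replicate 4 (0.0454), and its direction was higher without control replicate 1 (0.153), without LGK974 replicate 1 (0.281), without both libraries highest in Ttr (0.843), with the choroid covariate (0.147) and with the barrier covariate (0.0983). With an estimated correlation its adjusted p was 0.832. TGF-beta and BMP target genes had a median of -0.02, a mean of 0.01 and a test direction of higher (adjusted p = 0.225). Ribosomal protein genes had a median of -0.02 and a test direction of higher (adjusted p = 0.691), against a median of -0.05 over all genes. Of 23 replication-dependent histone genes 4 were measured, with a median of 0.02, and the sex-linked list held 1 measured gene, at -0.18, both too few to test.

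The pan-endothelial markers rose as a group, with 16 of 20 higher and a median log2 fold change of 0.16 (camera adjusted p = 0.000817; adjusted p = 0.62 with an estimated correlation). Pecam1 was at 0.44 (SE 0.15), higher in all 4 LGK974 libraries, and Tie1 at 0.17; without control replicate 2 the adjusted p was 0.151. Pericyte and smooth muscle markers fell as a group, 15 of 16 being lower, with a median of -0.28 (adjusted p = 0.00586; adjusted p = 0.62 with an estimated correlation). The brain pericyte gene Atp13a5 fell adjusted over the list alone (adjusted p = 0.0205), from 19.2 ± 0.263 FPKM to 10.4 ± 1.78 (log2 fold change -0.83, SE 0.16), but not over all genes. Vtn was at -0.37, Ndufa4l2 at -0.30 and Anpep at -0.30. The list mean was lowest in LGK974 replicate 2, without which the adjusted p was 0.0746.

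Markers of other cell types differed widely between libraries of the same group. Ttr, the most abundant choroid plexus transcript, was 6267 and 2583 FPKM in the control libraries and 673, 978, 1814 and 6819 in LGK974 replicates 1 to 4. All 8 measured choroid plexus and ependymal genes were lower with LGK974, with a median log2 fold change of -0.69 (camera adjusted p = 0.0652). Oligodendrocyte genes had 7 of 8 lower and a median of -0.40 (adjusted p = 0.0652), and Cldn11 followed the same order of libraries as Ttr, from 2.67 FPKM in LGK974 replicate 1 to 8.40 in LGK974 replicate 4. Both lists passed as lower with LGK974 under the 3 other scalings, at adjusted p-values of 0.0112 to 0.0391 for the choroid plexus and 0.0112 to 0.0432 for the oligodendrocyte genes, and without a filter (0.0254 and 0.00289). They passed without LGK974 replicate 4 (3.06e-05 and 4.77e-05) but not without control replicate 1 (0.657 and 0.958), and with an estimated correlation the adjusted p was 0.645 for both. The barrier list mean was lowest and the tip-like mean highest in LGK974 replicate 1, the library lowest in Ttr. With the choroid plexus genes as a covariate, the tip-like list had an adjusted p of 0.525 and the pericyte list 0.159. Without both libraries highest in Ttr, control replicate 2 is the only control left, so list calls in that fit rest on it alone. The Wnt target, barrier, tip-like and pericyte lists then stayed past camera's threshold in the same direction. The interferon and cytokine lists missed it. In the main fit none of these calls held with an estimated correlation (camera adjusted p = 0.62 for each).

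T and NK cell genes rose as a group, with 9 of 9 measured higher and a median log2 fold change of 0.63 (camera adjusted p = 0.0113; adjusted p = 0.645 with an estimated correlation), although Il2rb ran from 0.848 to 8.87 FPKM in control and from 1.29 to 17.7 with LGK974. Cd3g, Trbc2 and Nkg7 were at 0.63, 0.69 and 0.71, and the adjusted p was 0.958 without control replicate 1, 0.21 without LGK974 replicate 2 and 0.13 without LGK974 replicate 3. Microglia and macrophage genes had 13 of 18 higher and a median of 0.13 (adjusted p = 0.0409; adjusted p = 0.645 with an estimated correlation), with Fcer1g at 0.77, Cd14 and Ptprc at 0.46 and Tmem119 at -0.26. Ptprc, which encodes CD45, was 0.508 to 2.77 FPKM over the 6 libraries. Without both libraries highest in Ttr the microglia list fell as a group (adjusted p = 0.0231). Its adjusted p was 0.991 without control replicate 1, with the opposite sign, and 0.634 without LGK974 replicate 4, and under quantile and median-of-ratios scaling it missed the threshold. In these 2 lists 0 genes passed over all genes or adjusted over the list alone.

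Lists of B cells (3 of 5 lower, median -0.54, adjusted p = 0.587), fibroblasts (7 of 11 higher, median 0.04, adjusted p = 0.431) and glial tumour cells (5 of 8 lower, median -0.12, adjusted p = 0.225) did not pass. The B cell and glial tumour lists passed as lower without control replicate 1 (0.00145 and 0.0308) and without both libraries highest in Ttr (0.000648 and 0.0108), and with an estimated correlation their adjusted p was 0.832 and 0.645. Astrocyte genes had a median of -0.17, a mean of -0.01 and a test direction of higher (adjusted p = 0.616). Too few genes passed the filter to test precursors of oligodendrocytes (3 of 10, median -0.11), neurons (2 of 14, median -0.26), erythroid cells (4 of 8, median -1.13) and neutrophils (0 of 10). Without a filter the erythroid list passed as lower (0.0341), and the precursors (0.0612), neurons (0.825) and neutrophils (0.618) did not pass. The haemoglobin gene Hbb-bs was 96.0 ± 5.72 FPKM in control and 56.2 ± 41.9 with LGK974.

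**Figure D3:**
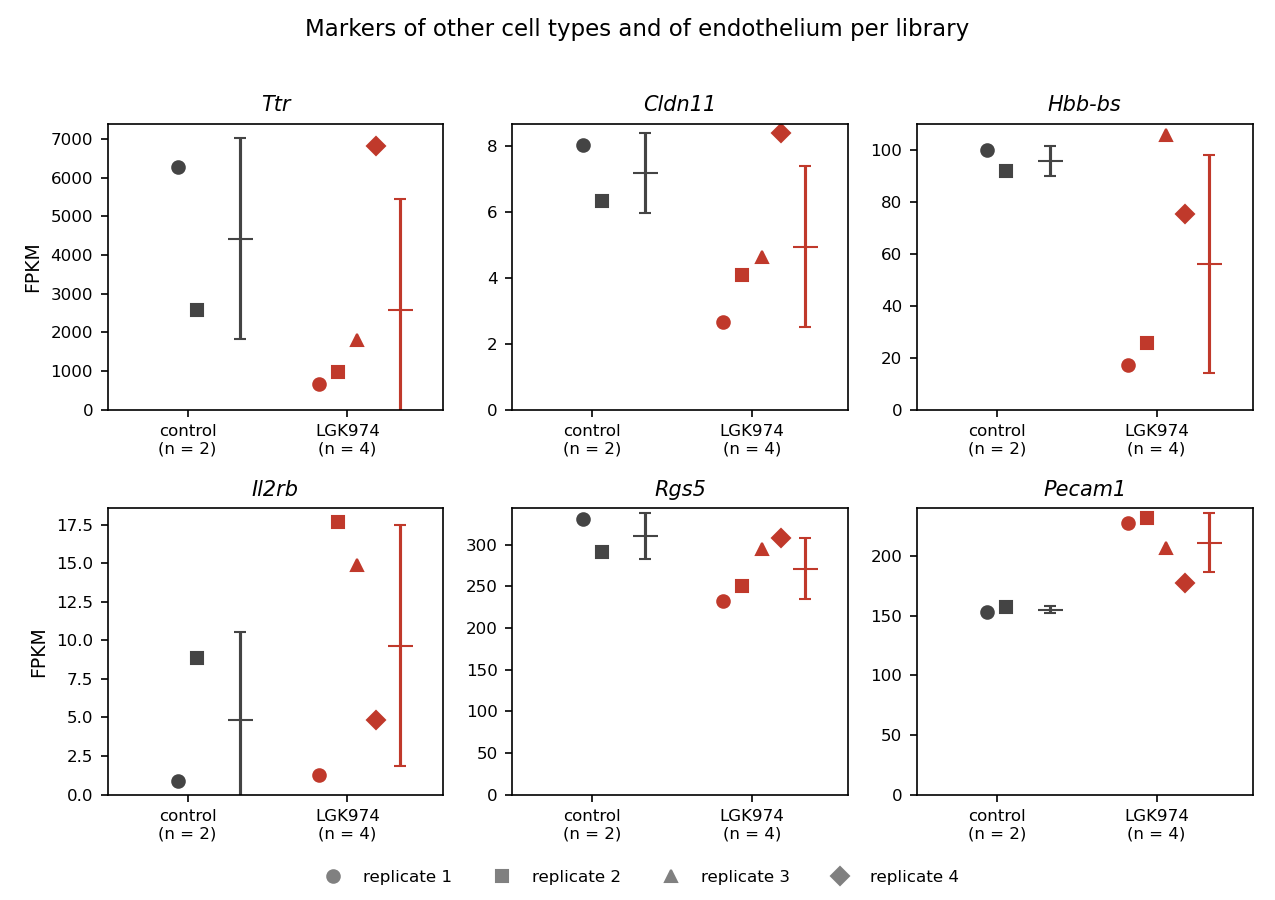
FPKM per library of Ttr (choroid plexus), Cldn11 (oligodendrocytes), Hbb-bs (erythroid cells), Il2rb (T and NK cells), Rgs5 (pericytes) and Pecam1 (endothelium), with control in grey (n = 2) and LGK974 in red (n = 4); symbols mark replicates and bars show mean ± SD, ending at the axis where they would pass below 0. Ttr ranges from 673 to 6819 FPKM within the LGK974 libraries, while all 4 lie above both controls for Pecam1.

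Of the 35 lists tested 17 passed camera at its preset correlation, 13 higher and 4 lower. In the 14 other splits of the libraries a median of 11 lists passed, with a lowest of 7 and a highest of 18. In the main fit with an estimated correlation 0 passed (smallest adjusted p = 0.62), and 0 passed fry's test of movement in 1 direction (smallest adjusted p = 0.143). Among the 17 lists called, the estimated correlation ran from -0.0608 (Notch) to 0.887 (T and NK cells). It was 0.552 for the barrier, 0.653 for the tip-like, 0.731 for the interferon and 0.876 for the cell cycle list. These 4 lie far above the preset 0.01, so the preset p-values of those lists are too small. For the Wnt target list it was 0.0529.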

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

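The tests of gene models, of correlation among choroid plexus genes, of barrier against tip-like transcripts and the counts over other splits of the libraries were chosen after the results were seen. The tests with covariates of Mfsd2a and of the Wnt targets, and of mitochondrial against choroid plexus transcripts, were written before their results. Of 114 groups of 4 LGK974 values examined, 4 held a library far from the others, and chance gives about 1 in 20.

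Plvap was 200 FPKM in LGK974 replicate 1 and 62.5 to 85.3 in the other LGK974 libraries, which all exceeded the control values of 32.1 and 33.0. Birc3 was 26.1 FPKM in the same library, against 19.4 to 20.5. The mean of the Wnt target list in this library was -0.471 relative to control, against -0.229 to -0.181 in the others. In LGK974 replicate 2 the mean of the pericyte and smooth muscle list was -0.705, against -0.19 to -0.098.

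Mfsd2a was lower in all 4 LGK974 libraries. A lower share of brain-type vessels among the sorted cells as the whole cause was argued against: with the mean of 10 barrier genes as a covariate, its log2 fold change was -0.812 (SE 0.16), against -0.996 without. Carry-over of choroid plexus was argued against in the same way, with -0.80 (SE 0.152). For the Wnt target list the median log2 fold change went from -0.276 to -0.258 with the barrier covariate. Of the 8 lowest targets 7 stayed negative, but they were picked as the lowest in the same data, so this says little. Each of the 8 moved upward, Lef1 from -0.582 to -0.289, Nkd1 from -0.59 to -0.27 and Notum from -0.39 to 0.056. The list stayed past camera's threshold at the preset correlation (adjusted p = 0.0377). In the main fit that call was lost with an estimated correlation (camera adjusted p = 0.62). The bound of -0.2 set beforehand was passed by no more than the bootstrap error of 0.058, taken over genes and not over libraries. The test therefore cannot tell whether the vessel mix was the whole cause. Reduced Wnt signalling in the endothelium is the biological difference that the design names and may account for both, but neither Mfsd2a nor any Wnt target passed the test over all genes, so it remains a hypothesis.

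Gsk3b and Snora7a fell with no overlap between the groups, and deposited gene values can depend on which transcripts were assembled. Another set of gene models for the control libraries should separate more genes by at least 0.8 on the log2 scale in the real split than in others. The real split had 10, against a median of 8 and a highest of 87 in the 14 others. The 87 came from pairing control replicate 1 with LGK974 replicate 4, the libraries highest in Ttr, so the comparison with the highest split is a loose bar. With 10 of 13450 genes so separated, a difference of this size across many tested genes was not seen. Smaller differences cannot be judged from this count. A difference limited to the transcripts of Gsk3b and Snora7a may still account for their fall and was not tested, as only values per gene were analysed. The 15 possible splits are too few for a share under 0.05: the real split called 2 genes and the highest other 9, and 5 of 15 called as many.

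Choroid plexus transcripts differed between libraries of both groups. Of the 8 measured choroid plexus and ependymal genes 6 were used, without Rarres2 and Aqp1. Over all 8, camera's estimated correlation was 0.692. The 6 genes followed each other closely, with a median Pearson r of 0.991 over their 15 pairs. Choroid plexus cells or RNA carried through the sort for CD31, a gate that should remove them, may account for the joint movement of these 6 genes. The mean of the mitochondrially encoded transcripts went with them (r = 0.898, exact permutation p = 0.025; rho = 0.714, p = 0.136; r = 0.776 without the 2 libraries farthest from the median), and adjusted over 4 correlations p was 0.025 and 0.136. The split that pairs control replicate 1 with LGK974 replicate 4, the libraries highest in Ttr, called 9 genes and 2392 at an unadjusted p under 0.05, against 2 and 546 in the real split, which points to a structure of the samples along this axis. No biological explanation was tested.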

How the results depend on the processing

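The fits without the 2 libraries highest in Ttr and with the choroid plexus or barrier gene covariates were chosen after seeing the data. Over 20 alternatives, 8 of 1623 values of the 82 named genes changed direction and 13 lost the threshold. Mfsd2a and Axin2 stayed negative throughout; as only 2 of the 82 genes passed at all, staying on one side of the threshold says little. The median of the endothelial markers, a value with no test, ran from 0.05 to 0.214; the list call was lost without control replicate 2. Genes lower numbered 2 in the main result, 5 without a filter, 1 with a mean FPKM of at least 5, 1 with the replicate block, 1 without both libraries highest in Ttr, 1 with the choroid covariate and 1 with the barrier covariate. With each library left out in turn the count ran from 0 to 3, higher genes from 0 to 2 and lists from 8 to 17. Where 1 control was left, it was assumed to vary like the LGK974 group. Lists past the threshold numbered 17, then 11 with the choroid covariate, 0 with an estimated correlation and 0 with fry. The stricter filter tested fewer genes and dropped Snora7a; the other causes were not tested. The replicate block called Gm26712 alone and 14 lists, among them immediate early genes as lower (camera adjusted p = 0.0164). The labels do not say that equal replicate numbers pair samples. Control replicate 1 deviated with LGK974 replicates 1 to 4 at correlations of -0.237, -0.163, -0.03 and 0.382. These values cannot settle pairing, as the deviations of 2 controls are mirror images. Gsk3b missed the threshold in 10 alternatives (adjusted p 0.0741 to 0.326) and Snora7a in 3 (0.0711 to 0.112). Reversed, none past a threshold, were, as log2 fold changes, Slc2a1 (0.026) and Cldn5 (0.055) without control replicate 1, Tnfrsf19 (0.028) with the barrier covariate, Pfkfb3 (0.068) with array weights, Ptprc (-0.036) and Il2rb (-0.314) without control replicate 1, and Ptprc (-0.068) and Il2rb (-0.167) without both libraries highest in Ttr; the cause was not tested. With each library left out in turn, Slc2a1 ran from -0.396 to 0.026, Cldn5 from -0.547 to 0.055, Ptprc from -0.036 to 0.951 and Il2rb from -0.314 to 2.103. Unknown read totals limit what can be said of genes near 1 FPKM. On simulated values 50.75% of genes changed by 1 on the log2 scale were recovered, but genes near 1 FPKM were not among those changed.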

Other observations

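The correlation between barrier and tip-like transcripts and the count of lists over other splits were tested after the pattern was seen.

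LGK974 replicate 1 held the highest values of several genes. Gpihbp1, which anchors lipoprotein lipase on capillaries of muscle and fat, was 35.1 FPKM there, against 1.58 to 6.09 in the other LGK974 libraries and 1.13 and 2.45 in control. Fabp4, a fatty acid binding protein, was 8.17 FPKM there and 0.27 to 0.767 in the other 5 libraries. The tip cell gene Esm1 was 100 FPKM there and 13.8 to 17.6 in the others, and Kcne3 was 30.6 FPKM against 0.669 to 3.001. Igfbp3 was 1461 FPKM there and ran from 188 to 798 in the others. These genes were named after their values were seen.

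Over all 6 libraries the mean of the barrier list and that of the tip-like list went in opposite directions (r = -0.934, exact permutation p = 0.0014; rho = -1, p = 0.0028; adjusted over 4 correlations 0.0056 and 0.0112). Without the 2 libraries farthest from the median r was -0.619, so the relation rests in part on LGK974 replicate 1 and control replicate 1. A candidate explanation is that the sorted cells held barrier-type and angiogenic vessels in different shares, and no test here separates this from a change within each vessel. The choroid plexus genes went the same way as the barrier list (r = 0.82, exact permutation p = 0.0236; rho = 0.886, p = 0.0333; adjusted 0.025 and 0.0444; r = 0.972 without the 2 farthest). They went against the tip-like list (r = -0.927, p = 0.0056; rho = -0.886, p = 0.0333; adjusted 0.0112 and 0.0444; r = -0.917 without the 2 farthest).

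For the lists, the 15 splits of the 6 libraries are too few for a share under 0.05. The real split had 17 lists past camera's threshold and the highest other split 18, with 2 of 15 splits, the real one included, giving as many. The 14 other splits called a median of 11 lists and never fewer than 7. At its preset correlation camera thus called lists under every grouping of these libraries.

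Egr2, an immediate early gene, was 15.6 and 2.06 FPKM in the control libraries and 13.5 to 24.3 with LGK974, while Fos and Jun of the same list had log2 fold changes of -0.24 and -0.41. The scaffold gene Apc, whose product works in the same complex as Gsk3b, was 8.29 and 9.42 FPKM in control and 5.43, 4.29, 2.10 and 6.72 with LGK974 (log2 fold change -0.88), and did not pass. Xist was 48.7 to 92.8 FPKM in all 6 libraries and the Y-linked gene Ddx3y at most 0.0521.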
